A study of Bos taurus with 9 samples.

How the data were processed

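The libraries came from bovine blastocysts, early embryos with a fluid-filled cavity, in 3 groups of 3. The control group was not vitrified. The other groups were vitrified, that is, cooled to a glass-like solid without ice, and warmed again, either without or with α-ketoglutarate (AKG), an intermediate of the tricarboxylic acid cycle. They are called AKG-free and AKG-treated below. When and at what concentration AKG was given is not given in the sources used here. Per the labels' protocols, RNA was isolated with a kit for very small samples, amplified with a SMART-Seq v4 low-input kit and sequenced as read pairs on an Illumina platform. The labels call the libraries single-cell but name the embryo as the source. The number of embryos behind a library is not given in the sources used here. Nothing in the labels says that libraries of a group came from separate embryo batches, so p-values measure only the spread between these libraries, which may be partly technical. The labels give no sequencing batch or date.

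Per the submitters' processing notes, cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR were used, with no role stated for each. Their settings, the genome build and the annotation version are not given in the sources used here. Per the file headers, the 9 tables of single libraries hold FPKM (fragments per kilobase of gene, scaled to the mapped fragments of the library), as the authors deposited them. A table of the whole series holds the same FPKM and, beside it, the count of each gene in each library as deposited by the authors. Its FPKM columns were identical to those of all 9 single-library tables. FPKM corrects for gene length and library depth but not for composition, so a few very abundant transcripts lower the values of all others. The labels do not state that counting used strand, so reads of overlapping genes on opposite strands could not be told apart. Reads of near-identical copies could have been divided among genes. PAG11 belongs to a large family of similar genes and COX7B2 has a close relative, so their values are uncertain in this respect.

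All tables list the same 47 genes, which the deposited series table presents as differentially expressed. Of these, 43 are protein coding, 3 are long noncoding RNAs and 1 is a pseudogene, and 12 have no symbol. The rule that chose them is not given in the sources used here. In all 47 genes the mean FPKM of the AKG-free group was the highest or the lowest of the 3 groups. The tests below ran within a list of genes presented as differing between these same libraries. Their p-values describe how far the groups separate for listed genes and are not independent evidence that a gene differs, and adjustment was over the listed genes tested. Genes outside the list were not analysed here, and no fold change or p-value of the authors was used.

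The sum of counts over 47 genes is not the depth of a library. The ratio of count to FPKM equals gene length times mapped fragments, and gave relative depth instead. Over the 13 genes with at least 100 counts in all 9 libraries, no gene deviated from its library's common factor by more than 0.79%. Relative depth ran from 0.793 to 1.17 around a mean of 1. Absolute depth is unknown. Where all libraries of a group had 0 counts, the fold was computed against a floor of 3 counts in each library, converted to FPKM, and is a lower bound. Floors cover counting error only, because amplified reads without molecular identifiers are not independent molecules.

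The test was limma (version 3.58.1, in R 4.3.3) on log2(FPKM + 1) with all 9 libraries in one fit, an intensity trend in the prior, and Benjamini-Hochberg adjustment at a threshold of 0.05. Fold changes on this scale understate the change of low genes. Genes with a mean below 0.5 FPKM over the 9 libraries were left out, which removed 18 genes and left 29. This test was fixed on the assumption that only FPKM was deposited. The counts found beside it were tested with edgeR's quasi-likelihood test (version 4.0.16), over the same 29 genes and over all 47, and with DESeq2's Wald test (version 1.42.0), with library sizes from relative depth. DESeq2 was run with its filter for outlying counts switched off and a mean dispersion fit, and edgeR without a dispersion trend. These count tests were added after seeing the data. The other alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, quantile normalization, centring on each library's median, no trend, the replicate number as a term, library weights, only the 6 libraries compared, and leaving out each library. The limma test, its filter, these other alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for joining and summaries, and matplotlib 3.10.9 for plots.

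The limma step was tested on simulated data for the comparison of AKG-free with control libraries. In each of 50 tables of 29 genes, 10 genes were changed. Counts were drawn with the real relative depths, with each gene's mean over the 9 libraries raised to at least 30, and with an assumed dispersion of 0.1. The step recovered 47.2% of 2-fold, 99.2% of 4-fold and 100% of 8-fold changes and called 1.26%, 1.89% and 2% of unchanged genes. These shares hold only for that assumed spread.

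Named genes were, per comparison, those with a symbol, an adjusted p below 0.05 and all 3 libraries of one group above all 3 of the other, up to 12 in each direction by size of change. Where none passed in either direction, the 5 largest changes each way among genes with separate libraries were named as missing the threshold. Up to 4 members of each of 35 gene lists, among them stress, metabolism, cell lineage and markers of other cell types, and 18 genes such as SOD1, CAT, POU5F1 and CDX2 were to be named as well. Of the lists, 3 held a listed gene, 1 each, and 0 of the 18 genes were listed. A set test needed 5 listed genes in a list, so none was run. Gene positions are those of the deposited tables. Assembly ARS-UCD2.0 served only for the number of protein-coding genes per chromosome.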

Results

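RNA sequencing gave transcript levels in bovine blastocysts for 3 control libraries, 3 libraries of blastocysts vitrified and warmed without AKG, and 3 libraries of blastocysts vitrified and warmed with AKG. The values covered 47 genes presented as differentially expressed, by a rule not given in the sources used here. Counts over these genes summed to 32230 to 38486 in control libraries, 55940 to 362783 in AKG-free libraries and 37428 to 50780 in AKG-treated libraries. Relative sequencing depth differed much less, from 0.793 to 1.17 over the 9 libraries, and absolute depth is unknown. S100A11 took 4.59% to 5.95% of these counts in control libraries, 9.51%, 48.19% and 50.35% in AKG-free libraries 1, 2 and 3, and 6.28% to 15.97% in AKG-treated libraries. Values are given as mean ± SD of 3 libraries unless stated. Positions follow the deposited annotation, whose build is not given in the sources used here.

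AKG-free vitrified blastocysts were compared with controls to ask which transcripts differ after vitrification and warming. CRYAB (ENSBTAG00000000434, chromosome 15, 22242326 to 22246349), a small heat shock protein that binds unfolding proteins, had no reads in the 3 control libraries and rose to 11.3 ± 5.30 FPKM, at least 303-fold higher. PAG11 (ENSBTAG00000022759, chromosome 29, 39438824 to 39456485), a pregnancy-associated glycoprotein of the ruminant trophoblast, rose from 0.984 ± 0.853 to 44.7 ± 22.0 FPKM. S100A11 (ENSBTAG00000015145, chromosome 3, 18727498 to 18733580), a calcium-binding protein, rose from 24.5 ± 0.945 to 1034 ± 913 FPKM, with 57.4, 1178 and 1866 FPKM in AKG-free libraries 1, 2 and 3. NPSR1 (ENSBTAG00000013768, chromosome 4, 62120709 to 62274639), the receptor of neuropeptide S, fell from 77.7 ± 48.6 FPKM to 0 counts in all 3 AKG-free libraries, at least 2531-fold lower.

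On the log2(FPKM + 1) scale, limma gave changes of 4.52 for PAG11 (SE 0.791, adjusted p = 0.0026), 4.31 for S100A11 (SE 1.14, adjusted p = 0.01), 3.54 for CRYAB (SE 0.40, adjusted p = 0.000254) and -6.01 for NPSR1 (SE 1.40, adjusted p = 0.00679). CCL27, a chemokine, had no reads in controls and rose to 6.90 ± 4.62 FPKM, a limma change of 2.83 (adjusted p = 0.00167). AIF1, an actin-binding protein best known from macrophages, rose from 8.52 ± 4.16 to 77.2 ± 73.9 FPKM. Its values in AKG-free libraries 1, 2 and 3 were 16.9, 55.0 and 160 FPKM. MOGAT1, which makes diacylglycerol, rose from 0.534 ± 0.335 to 7.55 ± 3.84 FPKM, and LIPH, a phospholipase, rose from 3.40 ± 1.18 to 14.9 ± 7.90 FPKM. NUCB2, a calcium-binding protein and precursor of nesfatin, rose from 112 ± 1.93 to 599 ± 304 FPKM. FKBP7, a protein-folding isomerase of the endoplasmic reticulum, rose 5.17-fold, and MANEA, a mannosidase of the Golgi, rose 4.04-fold by group means. COX7B2, a cytochrome c oxidase subunit, rose 4.35-fold by group means. It had 58.8, 285 and 322 FPKM in AKG-free libraries 1, 2 and 3 against 45.4 to 58.4 FPKM in controls. CYP27B1, the enzyme that activates vitamin D, rose from 0.141 ± 0.136 to 1.94 ± 1.84 FPKM, a limma change of 1.19 that became 0.71 without AKG-free library 3. ROGDI, a leucine zipper protein, fell from 27.7 ± 10.4 to 4.50 ± 1.55 FPKM, and CARMIL1, a regulator of actin capping, fell from 5.31 ± 3.22 to 0.654 ± 0.306 FPKM.

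**Figure D1:**
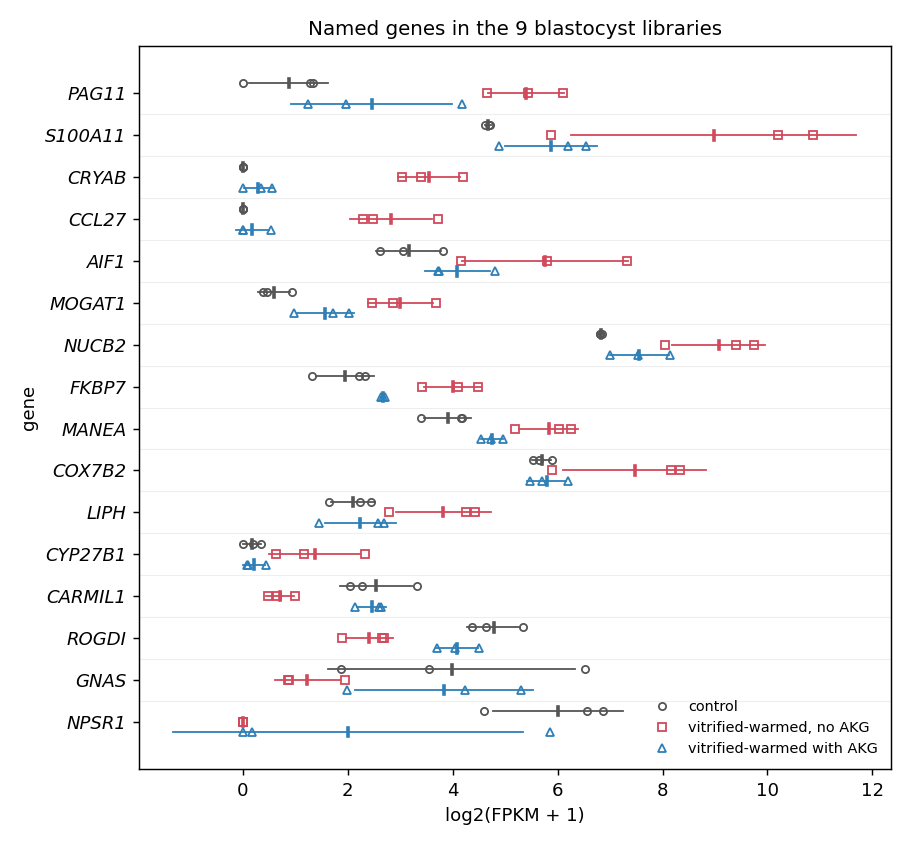
Expression of 16 genes on the log2(FPKM + 1) axis, with a symbol for each of the 9 libraries by group, a tick at each group's mean and a line of 1 SD to either side. CRYAB and CCL27 lie at 0 in the 3 control libraries and NPSR1 in the 3 AKG-free libraries, while AKG-free library 1 of S100A11 lies apart from libraries 2 and 3 and within the AKG-treated range.

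Among the 29 genes tested, limma found 14 higher and 5 lower in AKG-free libraries, and 17 higher and 7 lower at an unadjusted p under 0.05. Libraries of the groups did not overlap for 21 of the 29 genes. Chance gives 10% for genes not selected on these libraries, so that share is no benchmark for the listed genes. The genes without a symbol that passed were ENSBTAG00000050611 and ENSBTAG00000052882, which rose, and ENSBTAG00000038893 and ENSBTAG00000053922, which fell. ENSBTAG00000053922 had 4.87, 13.1 and 0 FPKM in control libraries 1, 2 and 3 and 0 in the AKG-free libraries, so its groups overlapped. The median log2 value of the tested genes was 1.11 higher in AKG-free than in control libraries. Relative to each library's median the split became 7 higher and 8 lower, and after quantile normalization 6 higher and 6 lower. Both methods take most genes as unchanged, but these genes are all presented as differing and 21 of the 29 were higher. They therefore shift the changes downward by construction, and these splits are no check on direction. With centring, CRYAB gave 2.43, PAG11 3.41, S100A11 3.20 and NPSR1 -7.13, all past the threshold, while AIF1, FKBP7, MANEA, COX7B2, LIPH and CYP27B1 missed it. Under quantile normalization NUCB2 gave -0.30, and AIF1 (0.97), FKBP7 (0.84) and MANEA (0.47) also missed the threshold, while S100A11 passed with 2.08. PAG11, CRYAB, CCL27 and MOGAT1 were also among the 6 higher genes, so most of COX7B2, LIPH and CYP27B1 missed as well. Without AKG-free library 2, 9 genes were higher, and S100A11 missed the threshold without AKG-free library 2 (adjusted p = 0.0717) or 3 (adjusted p = 0.0567). With edgeR over all 47 genes, of those with a symbol, AIF1 (adjusted p = 0.0536), NPSR1 and MANEA (0.0558), PAG11 (0.0779), COX7B2 (0.0816), LIPH (0.0832) and CYP27B1 (0.132) missed the threshold. Of the 9 fits that left out 1 library, AIF1 passed in 6, LIPH in 5, and COX7B2 and CYP27B1 in 3.

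Of the 35 gene lists, the heat shock list held CRYAB, the trophectoderm list held PAG11 and the imprinted gene list held GNAS. GNAS, which encodes a stimulatory G protein subunit, had 2.65, 90.6 and 10.8 FPKM in control libraries 1, 2 and 3 and 0.817 to 2.86 FPKM in the AKG-free libraries, and its limma change of -2.75 (SE 1.19) missed the threshold (adjusted p = 0.0579). It was -1.48 without control library 2 (adjusted p = 0.191). It passed without control library 1 (-3.81, adjusted p = 0.027), with a pseudocount of 0.1 (0.0367), with centring (0.0471), with edgeR over the 29 genes (0.0292) and with DESeq2 (0.000982). Adjusted over the list alone, which for 1 gene is the unadjusted limma p, the values were 8.78e-06 for CRYAB, 0.000269 for PAG11 and 0.0449 for GNAS. These genes are presented as differing between these same libraries, so the lists give no independent evidence of direction. No marker on the lists for cumulus, blood or sperm cells was among the listed genes, and those markers were not analysed here.

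AKG-treated vitrified blastocysts were compared with AKG-free vitrified blastocysts to ask which transcripts differ with AKG. CRYAB fell from 11.3 ± 5.30 to 0.243 ± 0.233 FPKM, a limma change of -3.25 (SE 0.40, adjusted p = 0.000522). CCL27 fell from 6.90 ± 4.62 to 0.152 ± 0.263 FPKM, a change of -2.65 (SE 0.442, adjusted p = 0.00275). PAG11 fell from 44.7 ± 22.0 to 7.10 ± 8.65 FPKM, a change of -2.94 (SE 0.791, adjusted p = 0.0226). It had 1.36, 17.1 and 2.90 FPKM in AKG-treated libraries 1, 2 and 3. CARMIL1 rose from 0.654 ± 0.306 to 4.55 ± 0.987 FPKM, a change of 1.75 (SE 0.446, adjusted p = 0.0197), and ROGDI rose from 4.50 ± 1.55 to 16.5 ± 4.89 FPKM, a change of 1.67 (SE 0.466, adjusted p = 0.0234).

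MOGAT1 and LIPH fell to 2.11 ± 1.07 and 4.06 ± 2.02 FPKM, and FKBP7 fell to 5.39 ± 0.185 FPKM. SYCP2, a component of the synaptonemal complex, rose from 0.183 ± 0.204 to 2.90 ± 2.59 FPKM, a limma change of 1.48 that became 0.97 without AKG-treated library 2, and TPRG1 rose from 0 counts to 0.909 ± 0.229 FPKM, at least 36.6-fold higher. These 5 genes had an adjusted p of 0.0442 in limma. S100A11 (to 64.3 ± 32.8 FPKM), NUCB2 (to 198 ± 77.7 FPKM) and COX7B2 (to 55.8 ± 15.3 FPKM) also passed in the lower direction, although their libraries overlapped. GNAS had 19.7 ± 17.8 FPKM with AKG, a limma change of 2.61 that missed the threshold (adjusted p = 0.0636) but passed with a pseudocount of 0.1 (adjusted p = 0.046) and with DESeq2 (0.00815). Adjusted over the list alone, the limma values were 1.8e-05 for CRYAB, 0.00467 for PAG11 and 0.0548 for GNAS, again on genes presented as differing between these libraries. NPSR1 had 57.3, 0 and 0.128 FPKM in the AKG-treated libraries 1, 2 and 3 and missed the threshold (adjusted p = 0.191).

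In all, limma found 6 genes higher and 10 lower with AKG, and 6 and 18 at an unadjusted p under 0.05, with separate libraries for 19 of 29 genes. The 10% that chance gives for unselected genes is no benchmark here either. Relative to each library's median the split was 5 higher and 2 lower, and after quantile normalization 4 higher and 2 lower; CRYAB, CCL27, CARMIL1 and ROGDI passed under both, while PAG11, MOGAT1, LIPH, FKBP7, S100A11, NUCB2, COX7B2 and TPRG1 missed under both. NUCB2 turned to 0.60 under quantile normalization. The median log2 value of the tested genes changed by -0.65 with AKG, so here both methods shift the changes upward by construction. With edgeR over all 47 genes, 0 genes passed in the lower direction. Of the named genes TPRG1 passed (adjusted p = 0.0165), while S100A11 and CARMIL1 (0.102), CRYAB, CCL27, MOGAT1, LIPH, FKBP7, NUCB2, COX7B2, SYCP2 and ROGDI (0.127) and PAG11 (0.187) missed. PAG11 also missed with edgeR over the 29 genes (adjusted p = 0.145) and with DESeq2 (0.0848), and MOGAT1 with edgeR over the 29 genes (0.0536). In limma without a filter, ROGDI (adjusted p = 0.0528) and S100A11, NUCB2, COX7B2, MOGAT1, LIPH, FKBP7, SYCP2 and TPRG1 (0.0748) missed. The number of lower genes was 3, 6 and 3 without control library 1, 2 or 3, 17, 3 and 5 without AKG-free library 1, 2 or 3, and 2, 3 and 2 without AKG-treated library 1, 2 or 3. The number of higher genes was 2 without AKG-free library 2, and 3, 0 and 1 without AKG-treated library 1, 2 or 3. CRYAB and CCL27 passed in all 9 of these fits, CARMIL1 in 7 (not without AKG-treated library 2 or 3), PAG11 in 6, ROGDI in 5, TPRG1 in 4, MOGAT1 and FKBP7 in 2, and LIPH, SYCP2, S100A11, NUCB2 and COX7B2 in 1. CRYAB and CCL27 had no reads in the 3 control libraries. Such libraries add no spread to the estimate over all 9, so the SE and p-values of both genes partly reflect the floor.

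AKG-treated vitrified blastocysts were compared with controls to ask what still differs after vitrification with AKG. The largest differences among genes with a symbol and separate libraries, all missing the threshold, were higher values of S100A11 (64.3 ± 32.8 against 24.5 ± 0.945 FPKM), MOGAT1 (2.11 ± 1.07 against 0.534 ± 0.335), MANEA (26.1 ± 3.97 against 14.5 ± 4.33), NUCB2 (198 ± 77.7 against 112 ± 1.93) and FKBP7 (5.39 ± 0.185 against 3.05 ± 1.37). Their limma changes ran from 0.72 for FKBP7 to 1.20 for S100A11, with adjusted p from 0.559 to 0.836. FKBP7 became 0.40 without control library 2, and NUCB2 went from 0.74 to 0.45 without AKG-treated library 1. ENSBTAG00000050611, without a symbol, differed by 1.35 (limma adjusted p = 0.559). CRYAB differed by 0.30 (95% interval -0.61 to 1.20), PAG11 by 1.59 (95% interval -0.20 to 3.37) and GNAS by -0.14 (95% interval -2.82 to 2.53). The log2(FPKM + 1) scale understates CRYAB. It had 0.464, 0.266 and 0 FPKM in AKG-treated libraries 1, 2 and 3 and no reads in controls, a mean at least 6.485-fold higher. PAG11 became 0.73 without AKG-treated library 2, and CRYAB 0.17 without AKG-treated library 1. CRYAB turned to -0.17 with centring, and GNAS ranged down to -1.20 without control library 1 and turned to 1.12 without control library 2 and to 0.78 without AKG-treated library 2.

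No gene passed limma in this comparison, 0 higher and 0 lower, with 0 higher and 1 lower at an unadjusted p under 0.05. That gene was NPSR1, named after its values were seen, with a change of -4.00 (SE 1.40, adjusted p = 0.542). edgeR's quasi-likelihood test also gave 0 higher and 0 lower, and DESeq2's Wald test gave 1 higher and 0 lower. The 1 higher gene was among the genes with a symbol named for this comparison in the paragraph before. Without AKG-treated library 1, limma gave 1 lower. Groups did not overlap for 6 of 29 genes, where chance gives 10% for unselected genes. The missed thresholds do not show equal levels: the 95% interval lay within 1 log2 unit of 0 for 1 gene, TPRG1, and reached beyond it for the other 28. For TPRG1 the bound does not limit a fall. Its control mean was 0.726 on the log2(FPKM + 1) scale, so even a loss of all reads stays within 1 unit.

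The vitrification and AKG changes were then set against each other gene by gene. All 19 genes that passed in the vitrification comparison had an AKG change of opposite sign, and 14 of them passed in both comparisons. All 10 genes that fell with AKG were among the 14 that had risen after vitrification, among them CRYAB, PAG11 and CCL27, where independent lists would share 4.83. Of the 6 that rose with AKG, 4 were among the 5 that had fallen, CARMIL1 and ROGDI with 2 genes without a symbol, where independent lists would share 1.03. Of these 2, ENSBTAG00000053922 had no reads in control library 3. These values for independent lists leave out the shared AKG-free libraries and the selection of the genes, so they are not the overlap to be had with no AKG effect, and that overlap was not computed.

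Across the 29 genes, which are not independent replicates, the changes correlated at r = -0.925. Both comparisons use the same AKG-free libraries, and 1000 simulated tables with no effect gave a median r of -0.517 (-0.808 to 0.02). Each gene was drawn independently, so the simulated values leave out genes that vary together within a library. The covariance was -4.09 against a simulated -0.295, a difference of -3.79. Signs were opposite for 100% of genes, against a simulated 65.5% (48.3% to 82.8%). The covariance difference is net of the shared libraries only as far as genes vary independently. Dividing the 3 AKG-free libraries would have left 1 of them in a comparison, so they were not divided, and part of the excess in overlap, correlation and sign may come from sharing them. None of these values allows for how the genes were selected.

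**Figure D2:**
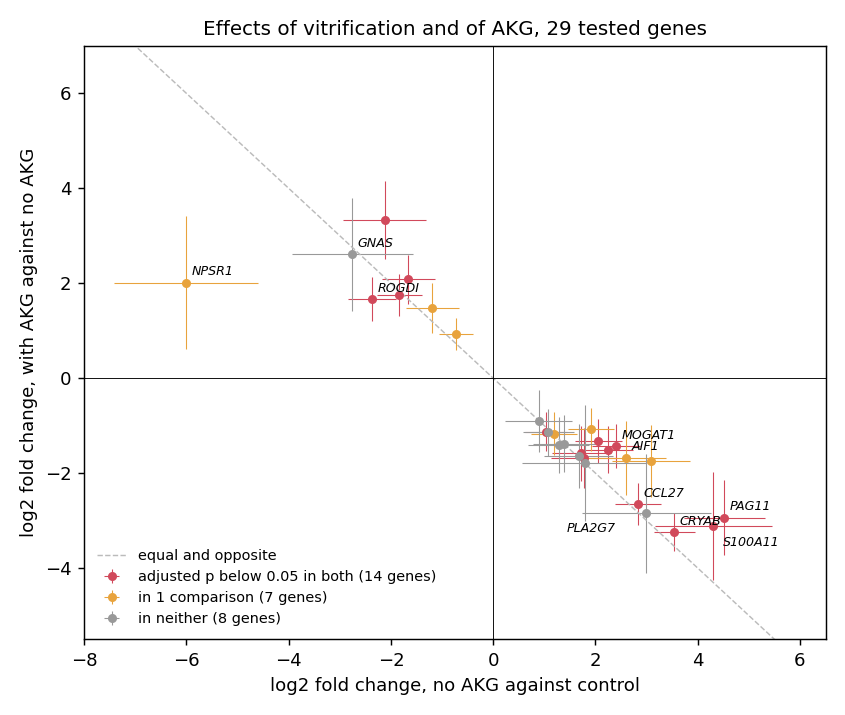
Vitrification change (x axis) against AKG change (y axis), in log2(FPKM + 1) units, for the 29 tested genes, with SE bars, colours for the 14 genes past the threshold in both comparisons, 7 in 1 and 8 in neither, and a dashed line where the changes are equal and opposite. Every point lies where the changes have opposite signs, which is the same as an AKG-free mean above or below both other means.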

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

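The tests of explanations and the splits of libraries in this part were chosen after the results were seen. Of the 18 genes left out for low values, 17 had reads in AKG-free libraries and none in the 3 control libraries. The genes are presented as differing between these libraries, so this is not independent evidence. Of the 18, 16 had reads in only 1 library. The 17 include AKR1D1 (2.35 FPKM in AKG-free library 1), TMEM217 (2.56 FPKM in AKG-free library 2), CCK (1.53 FPKM in AKG-free library 3) and PRSS48 (1.22 and 1.39 FPKM in AKG-free libraries 1 and 2), named after their values were seen. None of the 17 had reads in an AKG-treated library.

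Among all 47 listed genes, 18 had reads in exactly 1 library, always an AKG-free one: 1 gene in library 1, 11 in library 2 and 6 in library 3, with 66 to 3434 counts. Lower depth of the other AKG-free libraries is argued against, since relative depths were 1.105, 1.014 and 1.166 and, at equal level per depth, the smallest count expected there was 72 where 0 was observed. The 72 covers counting error only, and chance capture of few molecules before amplification stays open. A listing test in which 1 library decides remains a candidate explanation for why such genes are listed. Of the 18, DESeq2's Wald test over all 47 genes called 14 and edgeR's quasi-likelihood test called 0. DESeq2's filter for outlying counts, which acts on genes with reads in 1 library, was switched off. The 14 therefore depend on that setting, and the test was not run with the filter on. The submitters' notes name edgeR and not DESeq2, without saying which edgeR test was used. Whether the reads reflect biological differences between embryos after vitrification was not tested.

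AKG-free library 1 lay nearer to the controls than libraries 2 and 3: over the 21 tested genes with higher AKG-free values its median was 1.16 log2 units above the control mean, against 2.47 and 2.64. Over the 8 lower genes the medians were alike, -1.96, -1.99 and -2.09. Lower depth is argued against, with a relative depth of 1.105 against 1.014 and 1.166. A mislabelled control or AKG-treated library cannot be told apart: library 1 lay beyond all 6 other-group libraries for 17 of 29 genes, but library 1 is part of the AKG-free mean, which was the highest or lowest of the 3 in all listed genes. A difference in response between embryos stays open and was not tested.

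Selection of the listed genes on both comparisons and a reversal of vitrification changes by AKG cannot be told apart as sources of the opposite signs. The AKG-free mean was the highest or lowest of the 3 groups in all 47 listed genes, 38 and 9, but this restates the opposite signs. Genes outside the list, which could separate the explanations, were not analysed here.

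With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and the genes were presented as differing between the real groups, which favours the real split. For vitrification, 1 of 10 splits, the real one, gave as many genes as the real 19, and the highest other gave 0. For AKG, 1 of 10 did, with a real value of 16 and a highest other of 0. For AKG-treated against control the real value was 0 and the highest other 1, so all 10 gave as many by definition, which says nothing about chance.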

How the results depend on the processing

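The count tests (edgeR, DESeq2) were chosen after seeing the data; the other alternatives were planned. Genes higher after vitrification (14) became 6 with quantile normalization, 7 with centring, 8 with edgeR over all 47 genes, and 9 to 17 leaving out single libraries. Genes lower (5) became 8 with a pseudocount of 0.1, with centring, with edgeR over the 29 genes and with DESeq2, 2 with a mean of at least 5 FPKM, and 4 to 5 leaving out single libraries. Genes higher with AKG (6) became 3 without a filter, 2 at 5 FPKM or more, 2 with edgeR over 47 genes, and 0 to 5 leaving out libraries. Genes lower with AKG (10) became 3 without a filter, 1 at 5 FPKM or more, 2 with quantile normalization, 2 with centring, 18 with library weights, 4 with only the 6 libraries, 0 with edgeR over 47 genes, 20 with DESeq2, and 2 to 17 leaving out libraries. AKG-treated against control gave 1 higher gene with DESeq2 and 0 to 1 lower leaving out libraries. Genes of opposite sign (19 of 19 passing) became 12 of 12 at 5 FPKM or more, 12 of 12 with quantile normalization, and 13 to 21 leaving out libraries. Signs were opposite for all passing genes in each setting where this was counted, which leaves out the fit of only the 6 libraries. The correlation was -0.966 with edgeR, -0.974 with edgeR over 47 genes, and -0.947 to -0.84 leaving out libraries. Fewer genes are tested at 5 FPKM or more. Centring or quantile normalization on a list of mostly higher genes removes part of their change by construction. Otherwise the cause was not tested.

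With quantile normalization, directions turned for NUCB2 after vitrification (-0.30) and with AKG (0.60). That method gives each rank the same value in all libraries. In AKG-free libraries 2 and 3, S100A11 (1178 and 1866 FPKM) lay above NUCB2 (674 and 859). NUCB2 was the highest gene in the AKG-treated libraries and in control libraries 2 and 3. Its turns therefore follow from rank, although its FPKM was higher in all AKG-free than in all control libraries. In AKG-treated against control, directions turned for CRYAB with centring (-0.17) and for GNAS with library weights (0.50). GNAS also turned without control library 2 (1.12) and without AKG-treated library 2 (0.78), a range of -1.20 to 1.12. CRYAB had no reads in the controls, so its FPKM cannot be lower with AKG. Its turn follows from centring, which subtracted the 0.47 difference in library medians from its change of 0.30. GNAS had 2.65, 90.6 and 10.8 FPKM in control libraries 1, 2 and 3 and 17.7, 2.95 and 38.5 FPKM in AKG-treated libraries 1, 2 and 3. Leaving out control library 2 or AKG-treated library 2 therefore moved its change upward. The cause of its turn with library weights was not tested. Leaving out single libraries, named genes kept their side of the threshold in 122 of the vitrification fits, lost it in 21 and gained it in 1 (GNAS without control library 1), and in the AKG fits 55 kept it and 44 lost it. PAG11, CRYAB, CCL27, MOGAT1, NUCB2, FKBP7, MANEA, NPSR1, ROGDI and CARMIL1 passed in all 9 vitrification fits, S100A11 in 7, AIF1 in 6, LIPH in 5, and COX7B2 and CYP27B1 in 3.

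With the replicate block, AKG gave 3 higher and 3 lower genes. Replicate numbers are only a number here: same-number deviations correlated at -0.22 to 0.199, 1 of 9 pairs was over 0.1, and 2 of 9 libraries correlated best with their own number. The planned set tests were not run, since no list held 5 listed genes. Absolute depth is unknown, so for genes with 0 reads the limit is the floor of 3 counts per library.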

Other observations

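The edgeR test over all 47 genes, the draws over chromosomes and the count ratio in this part were chosen after the results were seen, as were the genes named. GATA5, a transcription factor of endoderm and heart development, had 0.449 ± 0.120 FPKM in controls, 0 counts in all 3 AKG-free libraries and 0.690 ± 0.485 FPKM with AKG. It lay below the filter. Over all 47 genes its adjusted p was 0.0204 for vitrification and 0.0165 for AKG in edgeR's quasi-likelihood test, but 0.227 and 0.0989 in limma without a filter.

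Other genes missed the limma threshold after vitrification. PYCARD, the adaptor of the inflammasome, had reads only in AKG-free libraries 2 and 3 (5.77 and 1.63 FPKM; limma adjusted p = 0.0579). PLA2G7, which inactivates platelet-activating factor, had 1.22, 4.87 and 147 FPKM in AKG-free libraries 1, 2 and 3 against 0.568 ± 0.216 in controls (limma adjusted p = 0.0569), and passed in edgeR over all 47 genes (adjusted p = 0.0497), where PYCARD (0.111), DDIT4L (0.0832) and GPD2 (0.187) did not. DDIT4L, an inhibitor of mTOR signalling, had 13.7 ± 11.5 against 2.60 ± 0.887 FPKM (limma adjusted p = 0.0503). Its AKG-free libraries 1, 2 and 3 had 12.3, 25.8 and 2.95 FPKM, with library 3 inside the control range of 1.58 to 3.20. GPD2, of the glycerol phosphate shuttle, had 11.3 ± 1.98 against 5.32 ± 3.38 FPKM (limma adjusted p = 0.0621).

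Chromosome 23 held 6 of the 43 protein-coding listed genes, 5 higher and 1 lower in AKG-free libraries, against 1.43 expected from its share of genes, a permutation p of 0.049 for the largest excess over 30 chromosomes, with all protein-coding genes rather than detectable ones as background. With the neighbours PLA2G7 and ANKRD66 counted once, that p was 0.198, so the excess does not hold without counting both. Of the 5 higher genes, TMEM217 and HMGCLL1 had reads only in AKG-free library 2 and ANKRD66 only in AKG-free library 3. On chromosome 23, ANKRD66 lies 6884 bp from PLA2G7 on the opposite strand and had 291 counts in AKG-free library 3 and 0 elsewhere, where the ratio to PLA2G7 in library 3 gives 8.4 expected in library 2, for counting error only.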
